A study of Homo sapiens with 6 samples.

How the data were processed

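H3K27me3, the histone mark written by Polycomb repressive complex 2 (PRC2), was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in H9 human embryonic stem cells, an established line, kept in the naive-state medium RSeT. Per the labels' protocols, cells received 25 nM of a control antisense oligonucleotide (CtrA) or of one directed at the LINE1 retrotransposon (L1KD), were then kept in RSeT with 10 nM DZNep and 5 nM TSA, and were collected 48 hours later. For each pulldown 70000 transfected cells were sorted on the FAM signal. The 6 libraries were 2 H3K27me3 ChIP libraries and 1 input library per oligonucleotide. The input DNA was 5% of a sample that the labels number as a replicate other than the 2 ChIP replicates, so each input stood for its oligonucleotide and not for a given pulldown.

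Per the submitters' processing notes, the authors used Bowtie2, SAMtools, deepTools and MACS3 with the hg38 build. Tool versions, read extension and the handling of duplicate reads are not given in the sources used here. The deposited values are signal, namely read coverage scaled to library size (CPM) per 50-bp bin, 1 column per library, per the file headers. CPM coverage is relative to the reads of its own library, and no spike-in scaling or input subtraction is named. A change of the mark by the same factor everywhere would therefore not show in these values. The 62525273 bins included 3318046 outside chromosomes 1 to 22 and X, and 5.92% of bins were at 0 in all 6 libraries. Column totals were 1993659 to 1997188, since a read was counted in about 1.99 to 2.00 bins. The smallest steps of the values gave the depth: 18.2 and 17.8 M reads (M, 1e6) in the CtrA ChIP libraries, 33.3 and 39.9 M in the L1KD ChIP libraries, and 136.6 and 85.1 M in the CtrA and L1KD inputs. Between 55.1% and 60.7% of bins above 0 held a whole multiple of 1 read to within 0.02 reads, so no count test was made.

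The mean CPM was taken over regions. The gene table used here, of the same assembly as the files, gives gene ends without strand, so the planned region of 2 kb either side of the gene start was replaced by 2 kb either side of both ends of each gene ("gene ends"), for protein-coding and lncRNA genes. Windows of 10 kb on chromosomes 1 to 22 and X were used for broad domains. Values were tested as log2(CPM + 0.00287), the pseudocount being 0.1 times the median ChIP signal of the windows, and fold changes are on that scale, which understates changes at low signal. Regions were tested where the mean of the inputs was 0.25 to 4 times the median input of the windows, which kept 37866 gene-end regions, 19840 of them of protein-coding genes, and 283785 of 296081 windows. A region was called enriched where the mean of the 4 ChIP libraries was at least 2 times the mean input. This mean uses both groups, but regions near the limit can pass through counting error, which was not alike in the groups. A median gene-end region held 42.1 and 37.1 reads in the CtrA ChIP libraries and 76.5 and 82.2 in the L1KD ChIP libraries, so counting error was larger in the CtrA libraries.

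The ChIP libraries of both oligonucleotides were compared by limma 3.58.1 in R 4.3.3 (moderated test with trend and robust options, two-sided, Benjamini-Hochberg threshold 0.05), without a replicate term. Gene lists were tested by limma's camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over 17 lists. Whether a list held more enriched members than other tested genes was tested by Fisher's exact test, two-sided. Of the lists, 16 were fixed by name and 1 by rule (protein-coding ZNF genes of chromosome 19). They held 401 named genes, 10 of them in more than 1 list. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. With 2 libraries per group, an exact permutation test cannot go below a two-sided p of 0.333. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Through the trend option, the SE of a region also draws on other regions of like signal. It can therefore exceed the spread of that region's own libraries.

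On simulated data for the 37866 gene-end regions, the fit recovered 98% of 2-fold and 100% of 4-fold falls, with 4 false calls, when replicates differed by ordinary noise. With the spread between replicate numbers measured in these libraries, it recovered 0% of both, while a fit with the replicate number as a block, one of the alternatives, recovered 99% and 100% with 20 false calls. The 2 replicate numbers differed in ChIP strength in both groups. Differences within replicate 1 and within replicate 2 (L1KD minus CtrA) are therefore given for lists and windows and for some of the named genes.

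Named genes were chosen by a rule. Among protein-coding genes with enriched ends it takes up to 12 rises and 12 falls past the threshold with the same sign in all 4 pairs of L1KD and CtrA libraries, or, where fewer pass, up to 6 of the largest same-sign differences, said not to pass. It adds up to 4 members with the largest difference from each list, and always ZSCAN4, LEUTX, TPRX1, DUXA, KLF17, DPPA3, GATA6 and HOXD13. Groups, tests, lists, this rule and most alternatives (a replicate block, pseudocounts, the input filter, other scalings, input subtraction, region sizes, a stricter enrichment limit, and leaving out each ChIP library) were fixed before the data were examined. Split by GC content and any count over LINE1 elements were not analysed here, as no genome sequence or repeat annotation was used. Some genes that the rule or a list would name are not reported here by name.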

Results

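H3K27me3 was measured in naive-medium H9 cells that had received a control (CtrA) or a LINE1 (L1KD) antisense oligonucleotide, in the presence of DZNep, a compound that lowers the PRC2 enzyme EZH2, and TSA, a histone deacetylase inhibitor. There were 2 ChIP libraries and 1 input per oligonucleotide. The CtrA ChIP libraries held 18.2 and 17.8 M reads and the L1KD ChIP libraries 33.3 and 39.9 M, so depth differed with the oligonucleotide. LINE1 RNA is not measured by these libraries, so the knockdown itself was not checked.

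By 10-kb windows the libraries differed more by replicate number than by oligonucleotide. The share of 10-kb windows with signal at least 2 times the input was 1.59% and 2.87% in CtrA replicates 1 and 2, and 0.421% and 2.16% in L1KD replicates 1 and 2. The group means were 2.23% ± 0.903 (SD, n = 2) for CtrA and 1.29% ± 1.23 (SD, n = 2) for L1KD, a difference of -0.936 percentage points that was smaller than the SD within the L1KD group and about as large as that within the CtrA group. With 2-kb windows, where the shallower CtrA libraries have more counting error, the shares were 4.32% and 3.69% in CtrA and 2.29% and 2.35% in L1KD, a difference of -1.69 percentage points that was larger than the gaps between replicates. The mean of the top 1% of windows stood 4.21 and 21.4 times above the genome median in CtrA replicates 1 and 2, and 2.58 and 19.1 times above it in the L1KD replicates. In both replicate numbers the L1KD library had the lower value of each measure. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333.

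H3K27me3 marked the developmental regulators that Polycomb is known to hold silent. All 39 HOX genes, which set body-axis identity, had enriched gene ends, at a median of 4.42 (log2 over input). All 38 neural and ectoderm regulators, such as EN1 and NKX6-1, were enriched, with a median of 3.34, as were 35 of 40 mesoderm and endoderm regulators, such as EOMES and FOXF1, with a median of 3.11. These values rest on the mean of 4 libraries, to which replicate 2 gave most signal. In L1KD replicate 1 the neural list stood at only 0.49 and the mesoderm and endoderm list at 0.37. Over all enriched gene ends the medians were 0.67 and 2.57 in CtrA replicates 1 and 2, and 0.05 and 2.47 in L1KD. Amnion genes (11 of 17), trophoblast genes (10 of 26), primed pluripotency genes (6 of 22) and fibroblast genes (5 of 17) also held more enriched members than the other tested genes. Over all tested gene ends, lncRNA genes included, 2745 of 37866 (7.25%) were enriched. The adjusted p of Fisher's exact test ran from 4.71e-44 for the HOX genes to 0.0125 for the fibroblast genes. This test takes genes as independent, whereas HOX genes lie in clusters, so their p is too small. The amnion and trophoblast lists share marked members and are not separate results. Many of the marked amnion, trophoblast and fibroblast members were transcription factors, among them CDX2, GATA3, HAND1, TWIST1 and TBX15, the last 5 chosen after their values were seen.

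Housekeeping, nucleolar, core and naive pluripotency genes had medians below the input, as did gene ends without enrichment in general. The medians of the latter were -0.39 and -0.49 (log2 over input) in the CtrA libraries and -0.38 and -0.46 in the L1KD libraries. RNA was not measured, so whether the listed genes were active in these cells is not known. No housekeeping gene of 23 and no nucleolar gene of 24 was enriched, and their medians were -1.33 and -0.94 (log2 over input). Core pluripotency genes had a median of -1.13 with 1 of 12 enriched (PRDM1), and naive pluripotency genes had a median of -0.55 with 1 of 22 enriched (TBX3). Both exceptions were named after their values were seen. None of these 4 lists differed from other genes in its share of enriched members by Fisher's exact test (adjusted p = 0.525, 0.525, 0.674 and 1). The 250 chromosome 19 ZNF genes, which encode zinc finger proteins, had a median of -0.64 with 2 enriched (ZNF440 and ZNF536, named in the same way), fewer than among other genes (odds ratio 0.103, adjusted p = 1.13e-05, Fisher's exact test).

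**Figure D1:**
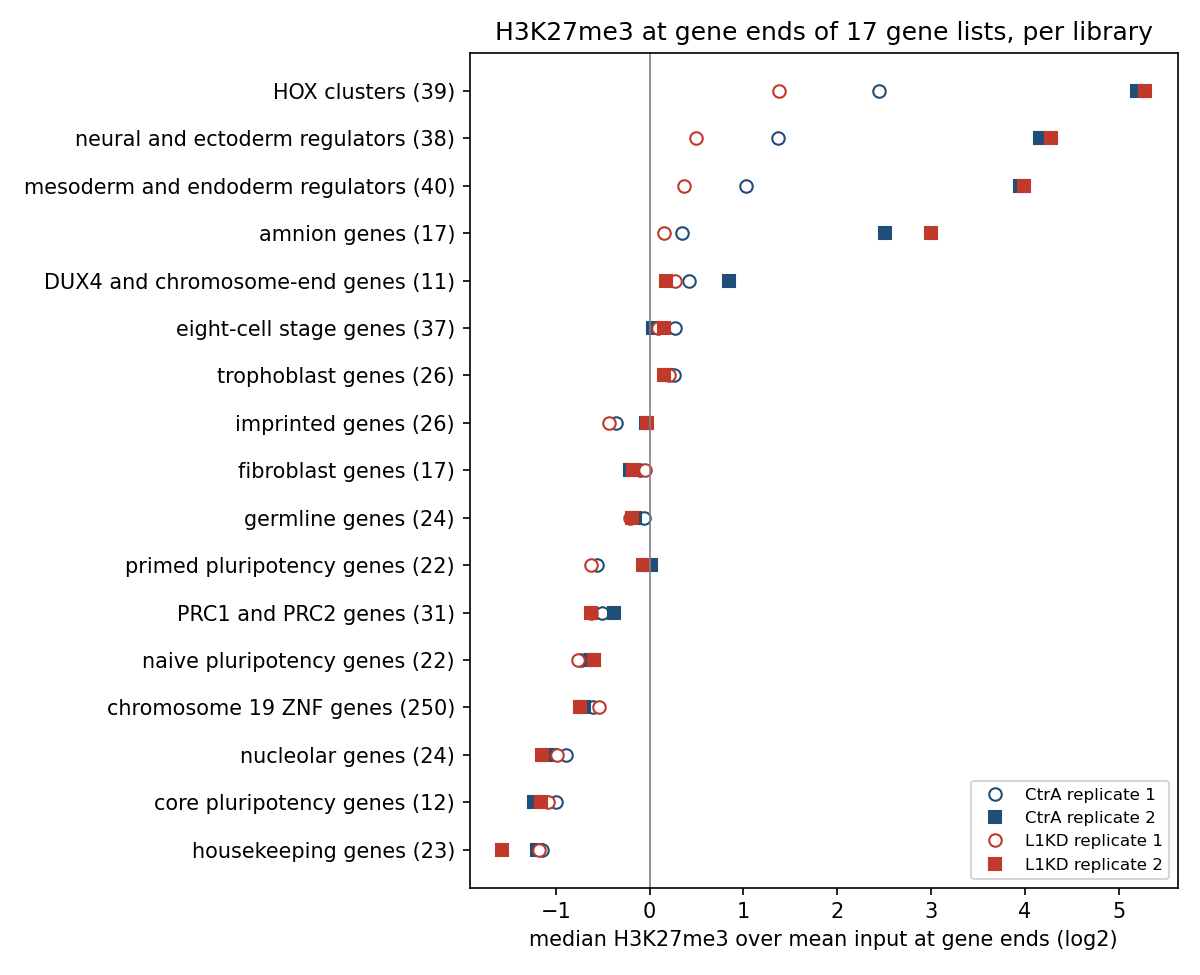
Median H3K27me3 over the mean input (log2) at the gene ends of 17 gene lists, 1 point per ChIP library, with the number of tested genes in parentheses; open circles are replicate 1, filled squares replicate 2, blue CtrA and red L1KD. The HOX clusters stand at 2.44 and 5.20 in the CtrA libraries and at 1.38 and 5.29 in the L1KD libraries, while the eight-cell stage genes stay between 0.04 and 0.27.

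The first comparison asked whether LINE1 knockdown altered H3K27me3 at these Polycomb targets. The pooled difference was negative, but it came from replicate 1, and it shrank after quantile normalization, to -0.05 (HOX), -0.09 (neural) and -0.04 (mesoderm and endoderm). As deposited, HOX genes had a median log2 difference (L1KD minus CtrA) of -1.13 within replicate 1, where 39 of 39 members were lower, and of 0.10 within replicate 2, where 3 of 39 were lower. HOXD13 (chromosome 2, 176087487 to 176095944, hg38), a posterior limb patterning gene, differed by -0.99 and 0.30. HOXC6 (chromosome 12, 54016888 to 54030823) had the largest pooled difference of the list, -0.75 with SE 3.69, from -1.46 and -0.05. Neural and ectoderm regulators showed the same split, with medians of -0.87 and 0.14. Mesoderm and endoderm regulators had medians of -0.71 and 0.09, and GATA6, an endoderm regulator on chromosome 18 (22169589 to 22202528), differed by -0.80 and 0.01. None of the 3 lists passed camera with all 4 libraries (adjusted p = 0.812 for each, 0.912 with an estimated correlation), and no member passed in the limma test, either over all gene ends or adjusted over the list alone. Leaving out 1 library turned the direction of the medians: without L1KD replicate 2 they were -2.46 (HOX), -2.22 (neural) and -2.11 (mesoderm and endoderm), and without L1KD replicate 1 they were 1.42, 1.52 and 1.46. Each of these fits set 1 L1KD replicate number against both CtrA numbers. At enriched gene ends replicate 2 stood above replicate 1 by a median of 2.12 (log2) in CtrA and 2.64 in L1KD. The turns therefore follow ChIP strength by replicate number and say nothing of the oligonucleotide.

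The second comparison concerned the eight-cell stage genes, which are transcribed at embryonic genome activation and which the study's title names. The median signal at these genes was near the input with either oligonucleotide. Only ZNF280A, RFPL2 and CCNA1 of 37 had enriched ends, which was no more than other genes (odds ratio 1.13, adjusted p = 0.795, Fisher's exact test); the last 2 were named after their values were seen. The median signal over input of the list was 0.27 and 0.04 (log2) in the CtrA libraries and 0.09 and 0.16 in the L1KD libraries. Gene ends without enrichment stood lower, at -0.39 and -0.49 in CtrA and -0.38 and -0.46 in L1KD. Several members of the list belong to families of near-identical copies, so reads could be split among copies and their values are uncertain. ZSCAN4 (chromosome 19, 57651476 to 57679152), a marker of this stage, stood at -0.04 over input with a difference of -0.08 (SE 0.46). LEUTX differed by 0.19 (SE 0.32), TPRX1 by -0.18 (SE 0.35) and DUXA by 0.13 (SE 0.45), and each of the 4 had opposite signs within the 2 replicate numbers. Of the list, 13 genes were lower and 7 higher in both replicate numbers. Its median difference was -0.08, with -0.16 in replicate 1 and -0.04 in replicate 2 (adjusted p = 0.812 by limma's camera and 0.948 by limma's fry), and 0 members passed, also adjusted over the list alone. After quantile normalization the list median was 0.19, in the other direction, and the list did not pass either.

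The other lists did not pass either. Among Polycomb genes themselves, 5 of 31 were enriched, RING1 among them. RING1, a catalytic subunit of PRC1 on chromosome 6 (33208500 to 33212716), was lower in both replicate numbers, by -1.05 and -1.09, with a pooled SE of 1.11. Its inputs were low, at 0.0097 and 0.0102 CPM beside a window median of 0.0325, near the lower limit of the filter. Its enrichment is therefore uncertain. Of the list, 13 genes were lower and 3 higher in both numbers, PHF19 among the latter, by 0.56 and 0.83. The list median was -0.21 (-0.19 and -0.06 within the replicate numbers). Imprinted genes had a median of -0.18 (-0.10 and -0.22), and the growth-restraining PHLDA2 was lower within both numbers, by -1.02 and -0.93 (SE 0.94). KCNQ1OT1, the antisense RNA of the same imprinted domain, was enriched and differed by -0.51 and -0.46; its region overlaps KCNQ1 and was not told apart from it. Of the germline genes 4 of 24 were enriched, and MAEL, a piRNA pathway gene, differed by -0.84 and -0.36. The list median was -0.10, with -0.08 in replicate 1 and 0.00 in replicate 2. Genes of chromosome ends, among them DUX4, the activator of the eight-cell program, had a median of -0.39 (-0.176 and -0.245 within the replicate numbers). The list median was -0.05 without CtrA replicate 2, -0.09 and -0.08 with flanks of 1 and 5 kb, and 0.06 after quantile normalization. DUX4 differed by -0.57 and -0.81. These copies share reads with near-identical repeats, so their values are uncertain. The list did not pass limma's fry (adjusted p = 0.502).

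The pooled median of the amnion genes was -0.34, from -0.76 and 0.16 within replicates 1 and 2. Primed pluripotency genes had -0.19 (-0.36 and -0.05), and trophoblast genes -0.15 (-0.25 and 0.14). Naive pluripotency genes had a pooled median of -0.15, although both replicate medians were slightly above 0 (0.02 and 0.01). Fibroblast genes had -0.01 (-0.09 and 0.04), nucleolar genes -0.01 (-0.08 and -0.06), chromosome 19 ZNF genes 0.02 (0.06 and -0.06) and core pluripotency genes 0.08 (0.01 and 0.20). Leaving out 1 library moved the trophoblast median between -0.19 and 0.21, the naive median between -0.24 and 0.11 and the fibroblast median between -0.10 and 0.48. The germline median then ran from -0.17 to 0.07 and the core pluripotency median from 0.01 to 0.35. Camera gave a positive direction for the amnion, trophoblast, fibroblast and germline lists, whose medians were below 0. The median over all gene ends was -0.04, so the amnion, trophoblast and germline medians were lower than it. Camera compares test statistics, in which members with a small SE weigh more. Among amnion genes, GABRP differed by 0.66 (SE 0.32) and MSX2 by -0.82 (SE 2.66). Among naive markers, DPPA5 differed by 0.69 (SE 0.34), DPPA3 by -0.22 (SE 0.34) and KLF17 by 0.09 (SE 0.35). TRIM28, a nucleolar list member that silences transposable elements, differed by -0.82 and -0.73, while NIFK of that list differed by 1.41 and 0.69. Of the nucleolar genes, 7 were lower and 5 higher in both replicate numbers. Housekeeping genes had a median of -0.10, with -0.10 in replicate 1 and -0.31 in replicate 2. Their camera p was 0.0132, which gave an adjusted p of 0.224, and 0.912 with an estimated correlation. By camera the list passed after quantile normalization (adjusted p = 0.00565) and after input subtraction (adjusted p = 0.00412). Its median input was 0.0456 CPM in CtrA and 0.0556 in L1KD, so subtraction by itself lowered the difference. Without L1KD replicate 1 the list median was -0.265. The call after quantile normalization did not hold in every fit tried with that scaling.

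Across all genes, 0 of 37866 gene ends passed the limma test, with 418 higher and 263 lower at an unadjusted p under 0.05. That balance turned with the scaling, to 303 higher and 532 lower after centring on windows without enrichment and to 452 and 1077 after input subtraction. Of the 2745 enriched gene ends 0 passed, with 0 higher and 6 lower at that unadjusted p. Leaving out 1 library mixes the replicate numbers unevenly, so ChIP strength enters the difference. The median over enriched gene ends was -1.43 without CtrA replicate 1 and 0.68 without CtrA replicate 2. It was 0.96 without L1KD replicate 1 and -1.69 without L1KD replicate 2. By the rule, the largest same-sign differences at enriched protein-coding genes were those of MUC4, a membrane mucin (chromosome 3, 195746771 to 195811929), at -1.31 (SE 0.41), the olfactory receptor gene OR2T3 at -1.03 (SE 0.34), TP53TG3E at -1.02 (SE 0.33), PRR20D at -0.97 (SE 2.33), LOC128966594, with -1.16 and -0.84 in replicates 1 and 2, and FAM90A16, with -0.77 and -1.19. The rule gave 1 gene in the other direction, the olfactory receptor gene OR4F5 at 0.11 (SE 1.01). The large SE of PRR20D and OR4F5 reflects other regions of like signal, since their own libraries were close within each group. PRR20D held 0.302 and 0.321 CPM in CtrA and 0.146 and 0.169 in L1KD. None of the 7 passed the threshold in this fit, which recovered 0% of simulated 2-fold falls at the spread between replicate numbers seen here. Most belong to families of near-identical copies, or contain tandem repeats as MUC4 does, so reads could be split among copies.

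Broad domains gave a like picture. Of 283785 windows 0 passed the limma test, with 2722 higher and 833 lower at an unadjusted p under 0.05. These were 5908 and 5262 after centring and 6343 and 5658 after quantile normalization. Of the 5282 enriched windows 0 passed in this fit without a replicate term, with 0 higher and 58 lower at that unadjusted p. The fit with a replicate block did call enriched windows and is given with the processing alternatives. Enriched windows were lower in L1KD, with a median log2 difference of -0.60 in replicate 1 and -0.18 in replicate 2, and 3951 of 5282 (74.8%) were lower in both numbers against 61 higher in both. Other windows had medians of 0.06 and 0.08. Within replicate 1 the difference grew with enrichment, from -0.42 in windows with a log2 enrichment of 1 to 1.5 to -1.01 above 3.5. Within replicate 2 it went from -0.24 to 0.06 over the same classes. Fits without 1 library again mixed the replicate numbers unevenly. The median over enriched windows was then -1.21 without CtrA replicate 1 and 0.41 without CtrA replicate 2. It was 0.62 without L1KD replicate 1 and -1.39 without L1KD replicate 2.

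**Figure D2:**
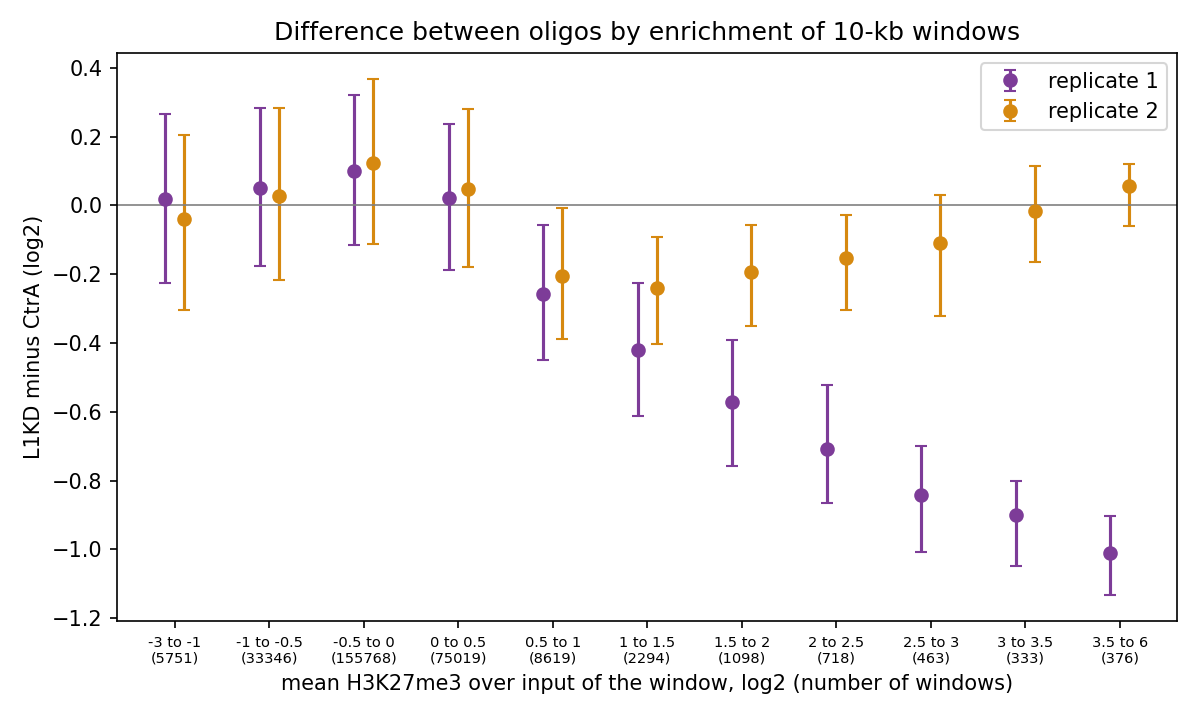
Log2 difference in H3K27me3 (L1KD minus CtrA) of 10-kb windows, by class of mean H3K27me3 over input (log2, with the number of windows); points are medians, bars run from the lower to the upper quartile of the windows, purple is replicate 1 and orange replicate 2. In windows enriched 3.5 or more the medians are -1.01 and 0.06.

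The title's reference to the nucleolus led to a comparison by chromosome. Enriched windows of the acrocentric chromosomes 13, 14, 15, 21 and 22, which carry the ribosomal DNA, had median differences of -0.57 and -0.17 in replicates 1 and 2, beside -0.61 and -0.17 on the other autosomes without chromosome 19. The relative difference was 0.01 with an SD of 0.03 over the pairs. Chromosome 19 had medians of -0.79 and -0.23, a relative difference of -0.10 (SD 0.09, 145 windows), which turned to 0.08 without L1KD replicate 1. Chromosome X had medians of -0.52 and -0.20. Within 5 Mb of a chromosome end 621 enriched windows had medians of -0.65 and -0.22, against -0.59 and -0.17 for 4661 windows farther inside. These values were described without a test.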

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

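All tests in this part were chosen after the values were seen. The ribosomal RNA gene arrays are the 45S units, around which the nucleolus forms, and the separate 5S array. They lay outside the tested regions because their input was 59.7 (45S units) and 11.6 (5S array) times the window median. They are raised here because their ChIP signal was above the input in both replicate 2 libraries. Over the 3 annotated RNA45SN units of chromosome 21 (8205988 to 8446572, hg38), signal over input was 1.90 and 3.86 in CtrA replicates 1 and 2, and 1.01 and 2.40 in the L1KD replicates. The mean log2 difference was -0.80 ± 0.157 (SD over 2 pairs), from -0.91 and -0.69. Over the RNA5S array of chromosome 1 (228610266 to 228646158, 17 annotated genes) signal over input was 3.27 and 16.1 in CtrA and 1.44 and 11.5 in L1KD, and the mean difference was -0.84 ± 0.489 (SD over 2 pairs), from -1.19 and -0.49.

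Another number of ribosomal copies, or another placement of reads, in the L1KD arm would lower the input too, but the input differed by 0.19 at the 45S units, in the other direction. That input came from other replicate samples than the pulldowns. The general shift of windows with like enrichment remains open: of 2526 such windows, 4.99% were lower than the 45S units in replicate 2 and 4.43% in replicate 1, near the edge of their spread but not outside its central 95%. Of them, 0.475% were lower than the units in both replicate numbers. A share lower in both cannot exceed either single share, and no limit was set for it, so it decides nothing. The arrays also pool more reads than a single window, which varies more. The 5S array was less extreme, with 10.6% and 9.16% of 415 windows lower, and 1.69% lower in both. A loss of the mark on ribosomal DNA after LINE1 knockdown may also account for the pattern and was not tested apart from this.

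Enriched windows were lower in L1KD in both replicate numbers. A weaker pulldown in L1KD replicate 1 would lower windows in proportion to their enrichment, and Spearman's rho of enrichment and difference across enriched windows was -0.59 there; windows are not independent replicates, and a real loss that grew with enrichment would look alike. In replicate 2 a weaker pulldown would give the same trend, but rho was 0.29, so that the windows with more enrichment were less low, whatever the scaling of the libraries. Removal of more duplicate reads from the deeper L1KD library would lower the windows with more signal, but rho of signal and difference was 0.32 in replicate 2. Both rest on 1 pair of libraries. Selection could also make windows near the enrichment limit look lower in L1KD, since they can pass through counting error in the shallower CtrA libraries. A median window held 57.2 and 44.1 reads in CtrA and 111 and 106 in L1KD. That effect was not tested. A lower level of H3K27me3 at moderately marked windows after LINE1 knockdown stays open too. The fit without a replicate term called 0 enriched windows. The fit with one, which called windows in that direction, is given with the processing alternatives.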

How the results depend on the processing

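The counts of 0 held with other pseudocounts, without the input filter, with centring and quantile normalization, with other region sizes and with stricter enrichment; input subtraction called 1 window. These zeros say little about stability, since the fit recovered 0% of simulated falls at the measured spread between replicate numbers. Of 289 alternatives for the lists, 278 kept their side of the threshold and 11 passed it; of 1307 for named genes, 8 passed it, and 93 had another sign. For the eight-cell list, the median ran from -0.16 to 0.19 and the adjusted p from 0.343 to 0.994 over 17 alternatives.

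The titles give replicate numbers 1 and 2 for both oligonucleotides, which makes 2 same-numbered pairs. Whether a number marks a shared preparation is not given in the sources used here. Same-numbered deviations correlated at 0.80 over gene ends and 0.91 over enriched ones. With the number as a replicate block, 68 gene ends passed (4 higher, 64 lower), 26 enriched gene ends (0 higher, 26 lower) and 156 windows (17 higher, 139 lower), and 266 of the 5282 enriched windows alone (0 higher, 266 lower). The gene ends included MUC4, RING1, PHLDA2, OR2T3, TP53TG3E and LOC128966594. Simulated data with the measured spread gave this fit 20 false calls. Under quantile normalization with the replicate block, chosen after seeing the data like the whole-gene and higher-end regions, the counts were 43 (33 higher, 10 lower), 1 and 9, with 15 enriched windows lower and 0 higher.

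Housekeeping genes, the 1 list called under either setting, had a median of -0.1521 after quantile normalization and -0.3209 after input subtraction. The first call was lost with the replicate block (adjusted p = 0.0519 by limma's camera), and its cause was not tested. For the second, the median input of the list was 0.0456 CPM in CtrA and 0.0556 in L1KD. Subtracting the 1 input per oligonucleotide therefore lowered the difference by itself. Leaving out 1 library mixes the replicate numbers unevenly, and the lone library is assumed to vary like the other group. Counts then ran from 0 to 75 (gene ends), 0 to 2 (enriched gene ends), 0 to 42 (windows) and 0 to 5 (lists: amnion, housekeeping, neural, mesoderm and endoderm without L1KD replicate 1; neural, mesoderm and endoderm, imprinted, PRC1 and PRC2, and primed without L1KD replicate 2). Medians ran from -1.867 to 1.395 (amnion), -0.265 to -0.04497 (housekeeping), -2.111 to 1.455 (mesoderm and endoderm), -2.217 to 1.525 (neural), -0.4807 to 0.2422 (imprinted), -0.4216 to 0.2473 (PRC1 and PRC2) and -0.4466 to 0.3566 (primed), and relative chromosome differences from -0.05039 to 0.1039 (acrocentric), -0.2709 to 0.07944 (19) and -0.1239 to 0.2873 (X). The difference in share of windows over input ran from -1.81 to -0.0677 percentage points. The split by GC content was not run. The CtrA libraries, at about 18 M reads, limit precision at weakly marked genes.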

Other observations

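The tests in this part were chosen after the results of the comparisons were seen. The prediction for the housekeeping list as a whole was written before its density-matched value was computed, and the one for replicate 2 alone after it. Beside random lists of gene ends with like ChIP signal (10000 per list), the neural and ectoderm regulators stood high in both replicate numbers, with a median at percentile 99.1 in replicate 1 and 99.97 in replicate 2. The mesoderm and endoderm regulators lay at 99.9 in replicate 1 and at 96.7, inside the central 95%, in replicate 2. Amnion and trophoblast genes lay at percentiles 99.9 and 99.7 in replicate 2 but at 38.6 and 73.8 in replicate 1. HOX genes lay at 2.54 and 78.3, and eight-cell stage genes at 41.1 and 91.5. These percentiles describe the 4 libraries and are no test of the oligonucleotide.

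Not all enriched windows shared the difference in ChIP strength between replicate numbers. In 866 of them replicate 2 was less than 0.5 (log2) above replicate 1, averaged over both oligonucleotides, and these had median differences (L1KD minus CtrA) of -0.42 and -0.35, with 85.6% lower in both numbers. Their median input was 0.0282 CPM in CtrA and 0.0276 in L1KD, against 0.0373 and 0.0389 over all enriched windows. Whether signal that did not follow ChIP strength is H3K27me3 was not tested, so these differences may not concern the mark. In 2256 windows with replicate 2 at least 2 above replicate 1 the medians were -0.81 and -0.06. Between 38 and 68 Mb of chromosome 9, a span around the centromere that is rich in duplicated sequence, 426 of 455 enriched windows were lower in both numbers, with medians of -0.57 and -0.37. On 261 alternate sequences of at least 200 bins, which the comparisons left out, the medians were -0.21 and -0.20, and that of the inputs was 0.02.

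Windows without enrichment differed with gene density. Those with no protein-coding gene within 0.5 Mb either side had medians of 0.11 and 0.15, and those with 21 to 40 genes had medians of -0.04 and -0.06, while the inputs went from -0.03 to 0.03. Spearman's rho across these windows was -0.12 and -0.16 in the ChIP pairs and 0.11 in the inputs; windows are not independent replicates. Whether this trend accounts for the lower values of the housekeeping genes was not settled. Their pooled median lay at percentile 31.5 of 10000 random lists matched on gene density, but also at 23.9 of lists drawn without matching, and they lay in regions of about the same density as other genes (a median of 14 against 13). The trend does not cover replicate 2 alone, where their median of -0.31 lay at percentile 1.15. In replicate 1 their median of -0.10 lay at percentile 28.8 of the density-matched lists, so only 1 pair of libraries departs. Beside lists of like ChIP signal they lay at percentiles 5.26 and 0.17. Base composition itself was not analysed here, and an effect of LINE1 knockdown on the housekeeping genes was not tested apart from it.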
